A study of Homo sapiens with 12 samples.

How the data were processed

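Polyadenylated RNA of 12 libraries of TeloHAEC cells was compared, 2 libraries for each of 3 lines (NT, TKO and NKO) on each of 2 coatings (IgG and DLL4). Per the labels, the coating solution held IgG or DLL4 at 2.5 mg/mL, RNA was taken after 24 hours, and the mRNA came from 140 ng of total RNA. The deposited values are TPM (tpm, transcript abundances scaled to a common total per library) per gene symbol, as made by the authors. The authors' processing notes name kallisto, edgeR and the build hg38. Their versions, the annotation behind the symbols and the way transcripts were summed to symbols are not given in the sources used here. The table held 35587 symbols. The TPM of a library summed to between 974989 and 977130, or 97.5% to 97.7% of the nominal total, so a small part of each library is in entries outside the table. TPM keep no record of the number of reads, so the depth is unknown and no counting interval or detection limit is given. The precision of a value is the spread between the 2 libraries of its group.

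The columns of the NT and TKO lines are numbered 2 and 3 and those of the NKO line 1 and 2, while the labels number the libraries of every group 1 and 2. Libraries are named here by the column numbers, and each group's columns were taken as that group's libraries. No pair of libraries was identical. Of the symbols 35389 were matched to GENCODE 29 (GRCh38) for position, biotype and transcript sequence and 198 were not, and 14 symbols stood as dates in the deposited table.

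Genes with a TPM of at least 1 in at least 2 libraries were kept (13299, of which 12159 are protein coding in GENCODE 29). The values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries, empirical Bayes moderation with a variance trend, two-sided tests, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The fit left 6 residual degrees of freedom, 10.8 after moderation. The 10 contrasts were DLL4 against IgG in each line, each knockout line against NT on each coating, and the differences between the DLL4 responses of each pair of lines. Errors of log2 changes are standard errors of the fit and errors of TPM are standard deviations (n = 2). Simulated data with the same design took normal noise at the fitted spread. Changes were placed in genes with a mean log2(TPM + 1) above 2. They therefore do not cover changes in genes at low levels, or a spread that differs between groups. On these data the fit recovered 96% of 100 genes with a true log2 change of 1 and 100% of those with a change of 2 for DLL4 against IgG in NT cells, with 18 false calls (8.41% of calls, 12565 genes). For the difference between TKO and NT responses it recovered 79% and 97%, with 12 false calls (6.38%, 12540 genes).

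Of 30 gene lists written from textbook knowledge, each with at least 5 measured genes was tested by limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists within a contrast. An estimated correlation and limma's fry were run beside it. The lists cover Notch targets, other pathways, endothelial subtypes, markers of other cell types and classes of abundant RNA. The retained response of a knockout line is the median change over the genes called in NT cells, signed by their direction there, as a percent of the NT median. Shared calls of the knockout lines were set against independent lists and against 100 simulated data sets in which unchanged groups met the same control libraries. Their direction was set against the DLL4 response in NT cells with different NT libraries for the 2 effects. Chromosome medians took protein-coding genes with a mean TPM of at least 5 and were compared with 10000 random gene lists, and regional medians took windows of 40 genes that started 20 genes apart. Transcripts were searched for unbroken runs of at least 17 C or G. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

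The design, the tests, the gene lists, the rule for naming genes and most of the alternative settings were fixed before the data were examined. The rule names TSPAN14, NOTCH1 and the Notch target genes, for each contrast up to 12 genes per direction with the largest change among those called, with a group mean of at least 5 TPM and no overlap between the libraries of the groups compared (no overlap rule for differences of responses), and of each list described up to 4 genes with the smallest p. Pseudogenes, antisense and clone entries and genes linked to sex were counted and not named, except KPNA2P2, which was singled out after its values were seen. The alternatives fixed at that point were a pseudocount of 0.1, no filter, a filter at a mean of 5 TPM, median-of-ratios rescaling, quantile normalisation, the replicate number as a block, no variance trend, a fit of only the libraries compared, and leaving out each library in turn. Alternatives added after the data were seen were leaving out KPNA2P2 and rescaling, leaving out the genes of chromosomes 8, 11, 18 and 21, and, for lists other than the Notch targets, both scalings and leaving out each library. No label says that a replicate number marks a shared day, so the replicate block is an alternative only.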

Results

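RNA was collected from TeloHAEC, a human aortic endothelial cell line immortalised with telomerase, after 24 hours on a coating of IgG or of Delta-like ligand 4 (DLL4). DLL4 is a membrane ligand of Notch receptors, and an immobilised ligand can activate the receptor on the cells above it. 3 lines were compared: a control line (NT), a line in which TSPAN14 was targeted with Cas9 (TKO) and a line in which NOTCH1 was targeted (NKO). TSPAN14 is a tetraspanin of the TspanC8 group, which binds the protease ADAM10 that cleaves Notch receptors. Each line and coating had 2 libraries, giving 6 groups and 12 libraries of polyadenylated RNA. The labels call the libraries of a group biological replicates and say no more about separate cultures, so the p-values here measure the spread between these libraries. The deposited values are TPM, a measure of transcript abundance scaled to the same total in every library, which keep no record of the number of reads, so the depth of each library is unknown. Of 35587 symbols, 13299 were tested. Across the tested genes, Pearson's r on the log2 scale was 0.987 to 0.992 between the libraries of a group and 0.937 to 0.975 between lines. The 1st principal component held 44.2% of the variance and separated the TKO libraries from the others. With 2 libraries against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333. All tests of genes are therefore moderated limma tests that pool the spread over the 12 libraries, and all changes are differences of log2(TPM + 1).

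The targeted genes were both still transcribed. TSPAN14 (chromosome 10, 80454166 to 80533123, plus strand, GRCh38) was at 204 ± 20.5 TPM (SD, n = 2) in NT cells on IgG and 179 ± 9.64 on DLL4. It was lower in TKO cells, at 137 ± 14.8 on IgG and 111 ± 2.98 on DLL4, and at 190 ± 15.8 and 176 ± 2.32 in NKO cells. Against NT on the same coating, TSPAN14 fell by 0.57 ± 0.10 (SE) in TKO cells on IgG (limma adjusted p = 0.0015) and by 0.68 ± 0.10 on DLL4 (adjusted p = 0.00039). In NKO cells its changes of -0.10 and -0.02 did not pass the test. NOTCH1 (chromosome 9, 136494433 to 136545786, minus strand) was at 18.7 ± 1.33 TPM in NT cells on IgG, 19.6 ± 3.64 in TKO cells and 17.4 ± 2.55 in NKO cells. On DLL4 it was at 28.1 ± 4.78 in NT cells, 22.7 ± 1.53 in TKO cells and 18.02 ± 2.09 in NKO cells. NOTCH1 thus differed between NKO and NT cells on DLL4 (-0.61 ± 0.16, limma adjusted p = 0.023), a call that ended without NT library DLL4 2 (adjusted p = 0.16) or NKO library DLL4 1 (adjusted p = 0.15). Its change on IgG was -0.10 (adjusted p = 0.72). An edit made with Cas9 can end protein production without lowering the mRNA, and the files hold no measurement of protein or of the edited sequence.

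The 1st question was what DLL4 does in the control line. Notch target genes were among those that rose most. HES4, a transcriptional repressor of the HES family, rose from 6.85 ± 1.00 to 117 ± 9.41 TPM (log2 change 3.91 ± 0.19). HEY2, a repressor linked to arterial fate, rose from 11.3 ± 0.30 to 56.4 ± 2.31 TPM. The ligand gene DLL4 itself rose from 5.25 ± 0.23 to 43.1 ± 3.44 TPM, and EFNB2, an arterial ephrin, from 0.31 ± 0.05 to 11.1 ± 0.97 TPM. The arterial connexin GJA4 was listed at 0 in both IgG libraries and at 6.42 and 4.27 TPM in the 2 DLL4 libraries. HES1 (0.93 ± 0.12), HEY1 (1.43 ± 0.21) and the netrin receptor gene UNC5B (1.26 ± 0.17) also rose. LFNG, a glycosyltransferase that modifies Notch receptors, fell by 1.51 ± 0.23, and CCND1, which encodes cyclin D1, fell by 0.85 ± 0.13. Of the 26 genes on the Notch target list 19 were tested, of which 12 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 0.93. The list rose against other genes by limma's camera (adjusted p = 3.1e-06; adjusted p = 0.26 with an estimated correlation). HES5, HEYL and NOTCH3 were on the list and lay below the expression filter.

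Other large increases in NT cells were those of SLC46A3, a lysosomal transporter, from 0.845 to 65.3 ± 4.81 TPM, TFF1, a secreted trefoil peptide, from 17.3 ± 3.87 to 400 ± 7.01 TPM, and IL33, a nuclear cytokine, from 0.32 ± 0.02 to 14.3 ± 0.30 TPM. ACP5 (3.50 ± 0.20), RND1 (3.39 ± 0.21), MASP1 (3.38 ± 0.27), IGFBP5 (2.85 ± 0.42) and the protease receptor F2RL1 (2.85 ± 0.25) rose too. The largest decrease among the genes named was that of FST, which encodes the activin inhibitor follistatin, from 57.7 ± 1.12 to 2.02 ± 0.08 TPM (-4.28 ± 0.15). CA2 (-2.85 ± 0.25), TMEM158 (-2.85 ± 0.20), PTPN7 (-2.70 ± 0.22), and MFNG, another glycosyltransferase of Notch receptors (-1.96 ± 0.09), fell as well. The metallothionein MT2A fell by 2.34 ± 0.06, and its paralogs share sequence with it. The limma adjusted p of each of these genes was 0.0012 or lower. In all, 2130 genes changed, of which 1021 rose and 1109 fell, and 355 of them changed at least 2-fold.

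Among the gene lists fixed before the data were examined, 13 of the 23 arterial genes tested rose and 3 fell (the same numbers adjusted over the list alone; median 0.47, camera adjusted p = 2.2e-06), with DLL4, HEY2, EFNB2 and GJA4, all shared with the Notch target list, as the members of smallest p. Proliferation genes went the other way: 24 of 47 fell and none rose (34 and none adjusted over the list alone; median -0.33, camera adjusted p = 2.3e-14). MCM2 (-1.03 ± 0.10) and MCM7 (-0.77 ± 0.08), parts of the replicative helicase, E2F1 (-0.79 ± 0.10) and CDC20 (-0.66 ± 0.08) were among them. Of 32 genes of mesenchymal cells and endothelial-to-mesenchymal transition 16 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.39, camera adjusted p = 9.0e-09), among them TPM1 (0.96 ± 0.07), COL5A1 (1.38 ± 0.11), CCN2 (1.14 ± 0.10) and THBS1 (2.39 ± 0.22). With an estimated correlation, the adjusted p of each of these 3 lists was 0.26. Of 44 genes of the extracellular matrix and basement membrane 17 rose and 5 fell (19 and 6 adjusted over the list alone; median 0.31, camera adjusted p = 5.1e-05, adjusted p = 0.37 with an estimated correlation), with COL4A1 up (1.05 ± 0.11) and EMILIN2 down (-1.46 ± 0.14). Of 46 genes at coronary artery disease loci 16 rose and 1 fell (20 and 5 adjusted over the list alone; median 0.22, camera adjusted p = 7.6e-05, adjusted p = 0.42 with an estimated correlation). They included CDKN2B, a cell cycle inhibitor (1.92 ± 0.12), ANGPTL4, an inhibitor of lipoprotein lipase (2.26 ± 0.15), and the VEGF receptor FLT1 (1.60 ± 0.11). Of the 30 lists, 15 passed camera's test in NT cells and 0 passed with an estimated correlation.

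The number of genes called depended on the libraries at hand. Without IgG library 2, IgG library 3, DLL4 library 2 or DLL4 library 3 of the NT line it was 1213, 958, 1056 or 1067, and a fit of the 4 NT libraries alone called 1085.

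**Figure D1:**
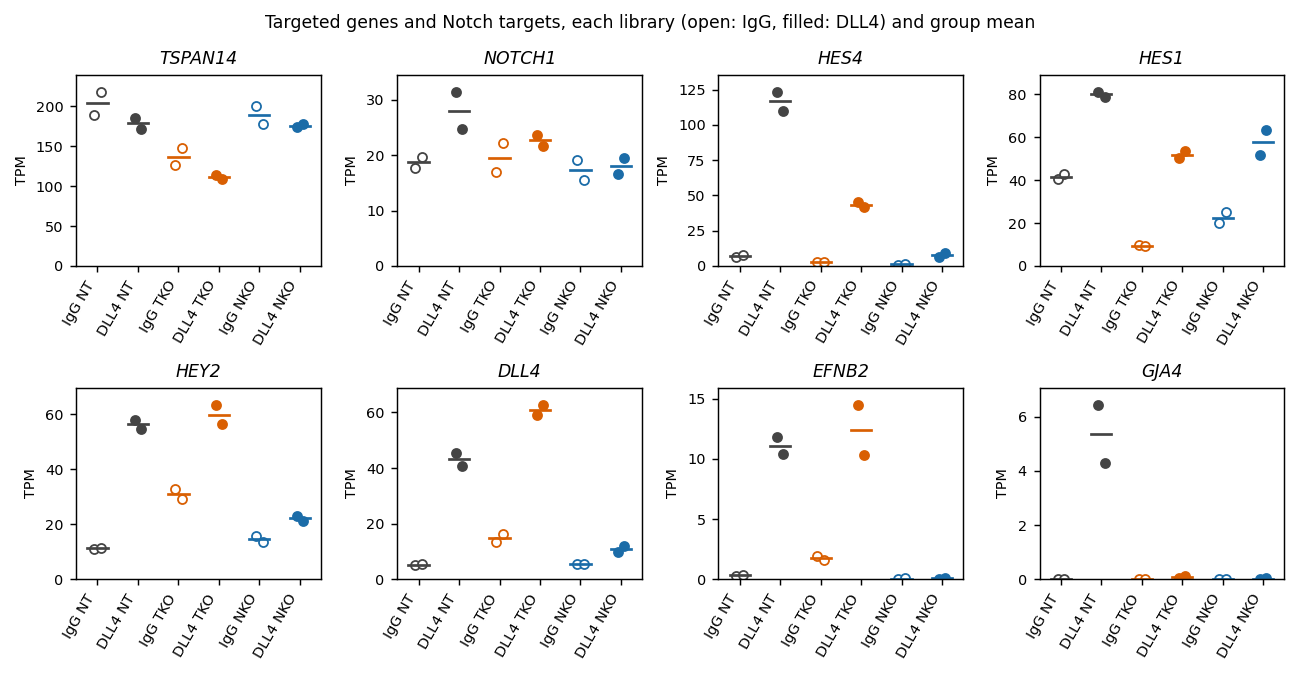
TPM of TSPAN14, NOTCH1 and Notch target genes in each of the 12 libraries (open points IgG, filled points DLL4), with a bar at the mean of each group. HES4 averaged 117 TPM in NT, 43.3 TPM in TKO and 7.73 TPM in NKO cells on DLL4.

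In TKO cells the ligand still raised Notch target genes. HES4 rose from 2.62 ± 0.28 to 43.3 ± 2.56 TPM (3.61 ± 0.19), HES1 from 9.33 ± 0.37 to 51.9 ± 2.33 TPM (2.36 ± 0.12), DLL4 from 14.8 ± 2.23 to 60.8 ± 2.50 TPM (1.97 ± 0.13) and EFNB2 from 1.75 ± 0.23 to 12.4 ± 2.91 TPM (2.27 ± 0.19). HEY2 rose by 0.93 ± 0.11 and CCND1 fell by 0.88 ± 0.13. GJA4 was at 0.0608 and 0.106 TPM in the 2 DLL4 libraries, and UNC5B (0.19 ± 0.17), JAG1 (-0.34 ± 0.17) and TMEM100 (-0.03 ± 0.21) did not pass the test. Of the 19 Notch target genes 8 rose and 1 fell (9 and 3 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0017; adjusted p = 0.52 with an estimated correlation). That call ended with a filter at a mean of 5 TPM (adjusted p = 0.12, median -0.03).

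Outside that list, SLC46A3 (3.88 ± 0.12), ART4 (3.11 ± 0.17), the phosphodiesterase gene PDE1A (3.07 ± 0.25), TFF1 (2.93 ± 0.30), the cytokine IL1B (2.60 ± 0.23), MEST (2.28 ± 0.27) and TMOD1 (2.20 ± 0.15) rose in TKO cells. FST fell from 311 ± 59.8 to 29.4 ± 0.53 TPM (-3.35 ± 0.15), and SH2D2A (-2.11 ± 0.13), the apoptosis inhibitor BCL2A1 (-2.01 ± 0.17), SEMA7A (-1.91 ± 0.17), RGS2 (-1.86 ± 0.18), STC1 (-1.82 ± 0.23) and CD274, which encodes the immune checkpoint ligand PD-L1 (-1.82 ± 0.22), also fell. Of 33 genes of the unfolded protein and ATF4 response 12 fell and none rose (13 and none adjusted over the list alone; median -0.15, camera adjusted p = 3.6e-07, adjusted p = 0.38 with an estimated correlation). ASNS and PSAT1, enzymes of asparagine and serine synthesis, fell by 1.80 ± 0.12 and 1.00 ± 0.10, and ATF4 by 0.55 ± 0.07. Of 30 p53 target genes 9 rose and none fell (16 and none adjusted over the list alone; median 0.35, camera adjusted p = 2.5e-06, adjusted p = 0.38 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 0.59 ± 0.09. Of 45 interferon response genes 6 rose and none fell (11 and 1 adjusted over the list alone; median 0.32, camera adjusted p = 3.4e-05, adjusted p = 0.52 with an estimated correlation). UBE2L6 (1.22 ± 0.16) and PSMB9, an immunoproteasome subunit (1.12 ± 0.18), were among them. In all, 866 genes changed in TKO cells, 546 up and 320 down. Without IgG library 2, IgG library 3, DLL4 library 2 or DLL4 library 3 of the TKO line the number was 542, 497, 348 or 302, and a fit of the 4 TKO libraries alone called 166. The pseudogene entry KPNA2P2, singled out after its values were seen, took 0.280% to 5.61% of a library's TPM, and with it left out and the libraries rescaled 459 genes rose and 418 fell.

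In NKO cells the same coating changed 104 genes, of which 68 rose and 36 fell. HES4 rose from 1.01 ± 0.43 to 7.73 ± 2.05 TPM (2.12 ± 0.19), HES1 from 22.4 ± 3.66 to 57.6 ± 8.28 TPM (1.33 ± 0.12), and DLL4 from 5.48 ± 0.22 to 10.8 ± 1.55 TPM (0.86 ± 0.13). The DLL4 call ended without NKO library IgG 1 (adjusted p = 0.099) or DLL4 2 (adjusted p = 0.13). EFNB2 was at most 0.131 TPM in the 4 NKO libraries, with a change of 0.04 ± 0.19. SLC46A3 (2.96 ± 0.12), F2RL1 (2.10 ± 0.25), IL1B (1.77 ± 0.23), ANGPTL4 (1.46 ± 0.15) and NID2, a basement membrane protein (1.19 ± 0.16), rose. FST (-1.97 ± 0.15), BCL2A1 (-1.71 ± 0.17) and ESM1, a marker of endothelial tip cells (-1.02 ± 0.13), fell. Of the 19 Notch target genes 4 rose and none fell (4 and none adjusted over the list alone), with a median of 0.04 and a camera adjusted p of 0.093. Without IgG library 2 of the NKO line that p was 0.046. Of 45 interferon response genes 1 rose and none fell (2 and none adjusted over the list alone), and the list passed camera's test (median 0.23, adjusted p = 2.5e-06; adjusted p = 0.70 with an estimated correlation) except without NKO library DLL4 2 (adjusted p = 0.052). Of 32 mesenchymal genes 2 rose and none fell (7 and none adjusted over the list alone, median 0.15, camera adjusted p = 0.00076, adjusted p = 0.70 with an estimated correlation). Of the 30 lists camera called 11 in NKO cells and fry 0. The number of genes called was 43 without IgG library 1, 37 without DLL4 library 2 and 0 in a limma fit of the 4 NKO libraries alone, where 865 genes had an unadjusted p under 0.05.

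**Figure D2:**
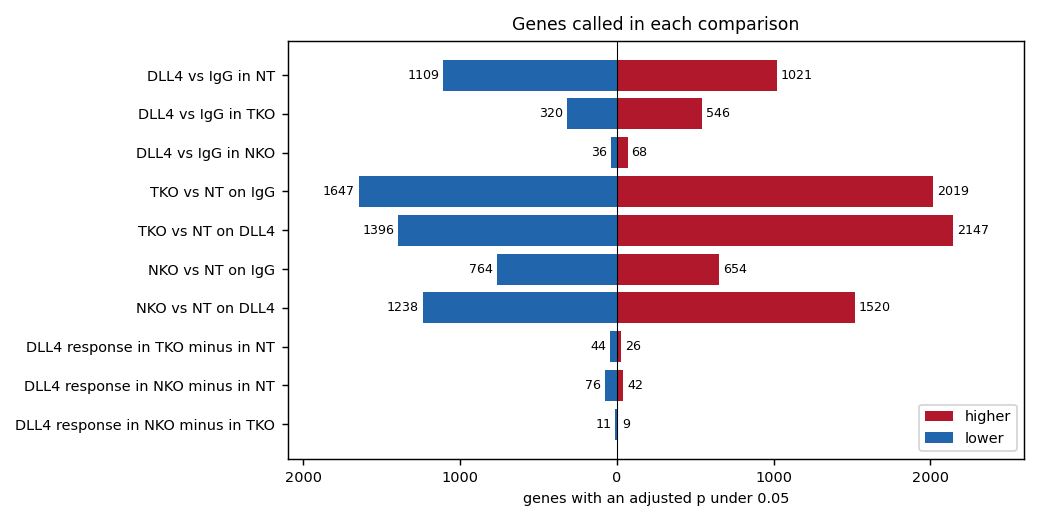
Genes up and down at an adjusted p under 0.05 in each comparison (bars from 0). DLL4 changed 2130 genes in NT, 866 in TKO and 104 in NKO cells.

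The responses of the 3 lines were compared directly. Each targeted gene was represented by 1 line. A difference in response therefore cannot be separated from other differences between the lines, and its p does not measure an effect of the targeted gene. Of the 866 genes called in TKO cells, 511 (59.0%) were called in NT cells in the same direction and 6 in the opposite one, where 41.9 shared increases and 26.7 shared decreases would follow from independent lists. Of the 104 genes called in NKO cells, 88 (84.6%) were called in NT cells in the same direction and 0 in the opposite one. Across the 2130 genes called in NT cells the median change in the direction seen there was 0.59 in NT, 0.22 in TKO (37.8%) and 0.17 in NKO cells (29.6%). Single DLL4 libraries gave 36.8% and 39.1% in TKO and 25.1% and 33.9% in NKO cells. These genes were chosen on the NT libraries, which favours large NT values. With genes chosen on 1 NT library of each coating and the NT response measured on the others, the share was 54.3% or 53.6% in TKO and 34.3% or 39.6% in NKO cells. That choice gave 373 or 500 genes with an NT median of 1.02 or 0.79, so both the genes and the measuring libraries differed. For the Notch target list, which was not chosen on these libraries and holds genes that went both ways, the median was 20.3% of that in NT cells in TKO cells (19.1% and 21.5% in single DLL4 libraries). In NKO cells it was 3.83%, and 12.3% and 7.40% in single DLL4 libraries. With 19 genes each median is the value of 1 gene: HES1 in NT (0.93), UNC5B in TKO (0.19) and EFNB2 in NKO cells (0.04). EFNB2 averaged only 0.046 and 0.073 TPM in NKO cells on IgG and DLL4. With a filter at a mean of 5 TPM the median in TKO cells was negative. These shares therefore compare different genes and do not measure how much of the response single Notch target genes kept.

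By the test of the difference itself, DLL4 changed 70 genes differently in TKO and NT cells, 26 of them towards a more positive and 44 towards a more negative value. HEY2 (-1.30 ± 0.15, limma adjusted p = 0.0075), IL33 (-2.67 ± 0.30), ACP5 (-2.50 ± 0.28) and CDKN2B (-1.55 ± 0.17) responded less in TKO cells. GJA4, listed at 0 in every IgG library, also responded less, at 6.42 and 4.27 TPM on DLL4 in NT cells against 0.0608 and 0.106 TPM in TKO cells. HES1 responded more in TKO cells (1.43 ± 0.17), from an IgG level of 9.33 TPM against 41.7 TPM in NT cells. MFNG (1.99 ± 0.13), which fell in NT cells, had a more positive value in TKO cells. It was at 138 ± 7.85 and 140 ± 11.7 TPM in TKO cells on IgG and DLL4. HES4 (-0.30 ± 0.27), DLL4 (-0.85 ± 0.19) and EFNB2 (-0.94 ± 0.27) did not pass this test. Without TKO library DLL4 3 the calls of HEY2 (adjusted p = 0.053), HES1 (0.053) and GJA4 (0.052) ended, that of HES1 also without NT library IgG 3 (0.0504), and those of ACP5 (0.080) and GJA4 (0.11) ended with a pseudocount of 0.1. The Notch target list was lower in the difference (median -0.33, 1 up and 2 down, 3 and 8 adjusted over the list alone; camera adjusted p = 0.0035, adjusted p = 0.50 with an estimated correlation), and with a filter at a mean of 5 TPM the call ended (adjusted p = 0.23). The arterial list was lower too (median -0.34, none up and 4 down, 2 and 8 adjusted over the list alone; camera adjusted p = 9.0e-06, adjusted p = 0.38 with an estimated correlation). The count of 70 became 108 with a filter at a mean of 5 TPM and 141 with quantile normalisation. It was 28, 13, 14 and 16 without NT libraries IgG 2, IgG 3, DLL4 2 and DLL4 3, and 24, 17 and 8 without TKO libraries IgG 3, DLL4 2 and DLL4 3.

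DLL4 changed 118 genes differently in NKO and NT cells, 42 towards a more positive and 76 towards a more negative value. EFNB2 (-3.17 ± 0.27, limma adjusted p = 0.00041), ACP5 (-2.84 ± 0.28), IL33 (-2.63 ± 0.29), RND1 (-2.47 ± 0.29), SLC46A3 (-2.20 ± 0.17), DLL4 (-1.95 ± 0.18) and HEY2 (-1.65 ± 0.15) responded less in NKO cells, as did HES4 (-1.79 ± 0.27, adjusted p = 0.013). GJA4, listed at 0 in both NKO libraries on IgG, was at 0 and 0.0486 TPM on DLL4 in NKO cells and also responded less. The HES4 call ended without NT library IgG 2 (adjusted p = 0.069) or DLL4 2 (0.084) or NKO library DLL4 1 (0.054) and with a pseudocount of 0.1 (0.18), which also ended that of GJA4 (0.082). FST (2.31 ± 0.21), MFNG (1.66 ± 0.13) and MT2A (1.36 ± 0.09), which fell in NT cells, had more positive values. Of the 19 Notch target genes 5 were lower in the difference and none higher (12 and 1 adjusted over the list alone; median -0.77, camera adjusted p = 1.5e-07). Of 23 arterial genes 7 were lower and 1 was higher (12 and 1 adjusted over the list alone; median -0.45, camera adjusted p = 2.0e-09), and of 32 mesenchymal genes 6 were lower and none higher (13 and none adjusted over the list alone; median -0.36, camera adjusted p = 1.1e-08). With an estimated correlation the adjusted p of these 3 lists was 0.22. The proliferation list was higher (median 0.31, 2 up and none down, 16 and none adjusted over the list alone; camera adjusted p = 7.3e-15, adjusted p = 0.26 with an estimated correlation). The count of 118 became 78 with no filter and 70 in a fit of the 8 libraries compared. Leaving out NT libraries IgG 2, IgG 3, DLL4 2 or DLL4 3 gave 45, 47, 31 or 46 genes, leaving out NKO libraries IgG 1, IgG 2, DLL4 1 or DLL4 2 gave 60, 72, 34 or 64, and leaving out either DLL4 library of TKO cells gave 67.

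Between the knockout lines 20 genes responded differently. EFNB2 (-2.23 ± 0.27, limma adjusted p = 0.010), PDE1A (-3.11 ± 0.35) and ART4 (-2.31 ± 0.24) responded less in NKO than in TKO cells. ASNS (1.62 ± 0.17) and MT2A (1.12 ± 0.09) had more positive values in NKO cells. Without NKO library DLL4 1 the calls of EFNB2 (adjusted p = 0.069), PDE1A (0.053) and ASNS (0.052) ended, that of EFNB2 also without TKO library DLL4 2 (0.054), and those of EFNB2 (0.24), PDE1A (0.055) and ART4 (0.94) ended with a pseudocount of 0.1. HES1 (-1.03 ± 0.17, adjusted p = 0.062), HES4 (-1.50 ± 0.27, adjusted p = 0.087) and DLL4 (-1.11 ± 0.18, adjusted p = 0.061) did not pass. Of the 19 Notch target genes 1 was lower and none higher (4 and none adjusted over the list alone; median -0.24, camera adjusted p = 0.00016, adjusted p = 0.60 with an estimated correlation). The unfolded protein and ATF4 list was higher (median 0.21, 2 up and none down, 6 and none adjusted over the list alone; camera adjusted p = 2.2e-09, adjusted p = 0.41 with an estimated correlation). Of the 20 genes 9 were higher and 11 lower, with median-of-ratios rescaling 7 and 14. A limma fit of the 8 libraries compared called 0, with 681 genes at an unadjusted p under 0.05, and no filter gave 33. Without NT libraries DLL4 2 or DLL4 3 the count was 12, without TKO libraries IgG 2, IgG 3, DLL4 2 or DLL4 3 it was 11, 10, 8 or 6, and without NKO libraries IgG 2 or DLL4 1 it was 12 or 2.

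**Figure D3:**
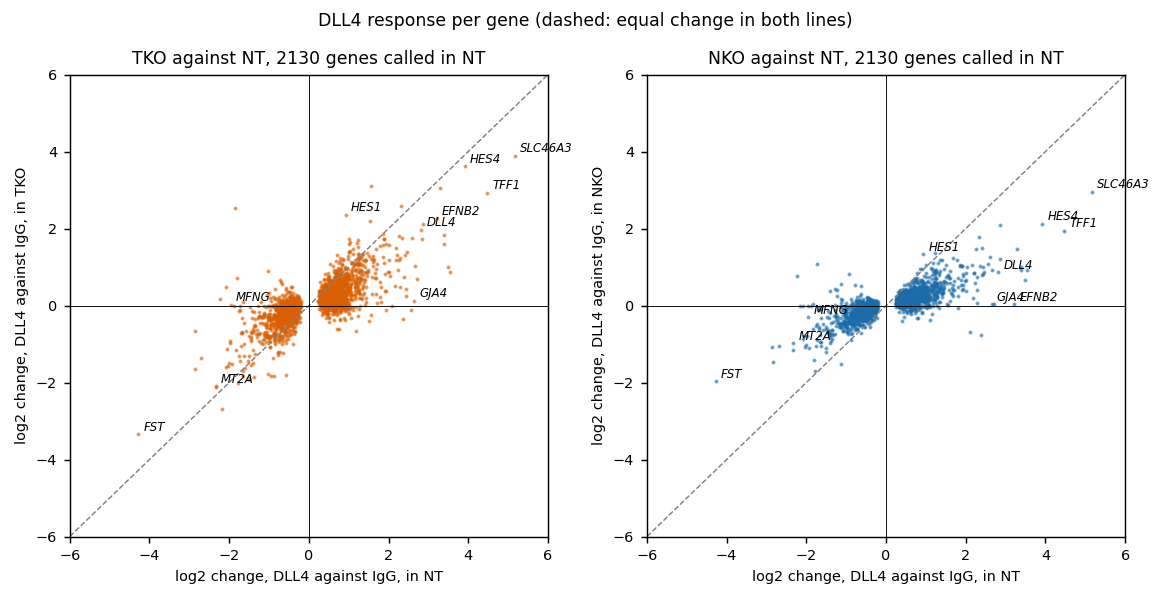
Log2 change on DLL4 against IgG in NT cells (horizontal axis) and in TKO or NKO cells (vertical axis) of each of the 2130 genes called in NT cells (points), with a dashed line where both changes are equal. The median change in the direction seen in NT cells was 0.59 in NT, 0.22 in TKO and 0.17 in NKO cells.

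The knockout lines also differed from NT cells on IgG, without added ligand. In TKO cells on IgG 3666 genes differed, 2019 up and 1647 down. POSTN, a secreted matrix protein, was at 265 ± 49.6 TPM against 0.24 ± 0.22 in NT cells (7.74 ± 0.15), TFPI2, a protease inhibitor, at 1250 ± 37.9 against 6.52 ± 1.53, the receptor tyrosine kinase AXL at 114 ± 24.3 against 0.16 ± 0.03, and OCIAD2 at 203 ± 22.7 against 2.81 ± 1.33. RAB34 (5.23 ± 0.21), GPX3, a secreted glutathione peroxidase (4.82 ± 0.22), HOXB8 (4.73 ± 0.14) and GPAT2 (4.71 ± 0.13) were higher too. DNER, a membrane protein with EGF repeats that has been described as a Notch ligand, was at 0.02 ± 0.03 TPM against 63.5 ± 0.58 (-5.98 ± 0.17). LRRC38 (-5.80 ± 0.41), VAMP8 (-5.64 ± 0.16), SCUBE1 (-5.33 ± 0.19), RGS5 (-5.25 ± 0.12), TFF3 (-5.01 ± 0.48) and IGFBP5 (-4.28 ± 0.42) were lower. On DLL4 3543 genes differed, 2147 up and 1396 down. POSTN (8.19 ± 0.15), TFPI2 (7.42 ± 0.53), AXL (5.94 ± 0.29) and DNER (-6.61 ± 0.17) were again among the largest differences, with IGFBP1 (5.58 ± 0.30), the transcription factors PPARG (-4.48 ± 0.15) and FOXF1 (-4.04 ± 0.23), and ANGPTL4 (-4.37 ± 0.15). The count on IgG was 2424 without NT library IgG 3 and 2245 in a fit of the 4 libraries compared, and the count on DLL4 was 2315 without TKO library DLL4 2.

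Single Notch target genes differed in both directions in TKO cells. On IgG, HES1 (-2.05 ± 0.12) and HES4 (-1.11 ± 0.19) were lower, and HEY2 (1.38 ± 0.11), DLL4 (1.33 ± 0.13), EFNB2 (1.07 ± 0.19), SOX17 (1.22 ± 0.13), CCND1 (0.96 ± 0.13) and NOX4 (2.19 ± 0.21) were higher. CXCR4 was at 2.35 and 4.14 TPM in the IgG libraries of TKO cells and listed at 0 in all NT and NKO libraries. That made 7 of 19 up and 3 down (7 and 3 adjusted over the list alone), a median of 0.00 and a camera adjusted p of 0.57. By limma's fry, which asks whether the genes of a list move one way on balance, the adjusted p was 0.032. On DLL4 6 were up and 7 down (median -0.07, camera adjusted p = 0.43), with HES4 (-1.41 ± 0.19), JAG1 (-1.51 ± 0.17) and UNC5B (-1.55 ± 0.17) lower and NOX4 (2.29 ± 0.21) higher. CCND1 and NOX4 lie on chromosome 11, whose genes were higher as a whole in TKO cells. Without the genes of chromosomes 8, 11, 18 and 21 the adjusted p on DLL4 was 0.041.

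Of 70 cytosolic ribosomal protein genes 50 were lower and 5 higher in TKO than in NT cells on IgG (57 and 5 adjusted over the list alone; median -0.31, camera adjusted p = 1.5e-13), and on DLL4 2 were lower and 6 higher with a median of -0.06 that did not pass, except without the genes of chromosomes 8, 11, 18 and 21 (median -0.08, camera adjusted p = 0.041). The ribosomal protein genes held 12.6% and 11.2% of TPM in TKO libraries IgG 2 and IgG 3. In NT libraries IgG 2 and IgG 3 they held 14.2% and 14.3%. TKO library IgG 3 also held the largest share of KPNA2P2 (5.61%). Of 49 oxidative phosphorylation genes 21 were lower and 8 higher on IgG (27 and 8 adjusted over the list alone; median -0.21, camera adjusted p = 0.00052), the exception of smallest p being SDHD (1.40 ± 0.09) on chromosome 11. Of 23 arterial genes 10 were higher and 2 lower on IgG (12 and 3 adjusted over the list alone; median 0.30, camera adjusted p = 0.0047), with DEPP1 (3.68 ± 0.17), BMX (2.03 ± 0.12) and SERPINE2 (1.54 ± 0.10) the highest by p. With an estimated correlation, the adjusted p of these 3 lists on IgG was 0.88. On DLL4, 22 of 47 proliferation genes were higher and none lower (31 and none adjusted over the list alone; median 0.28, camera adjusted p = 1.4e-07), including TYMS (1.34 ± 0.07) and E2F1 (1.06 ± 0.10). Of 46 genes at coronary artery disease loci 17 were lower and 4 higher on DLL4 (18 and 5 adjusted over the list alone; median -0.21, camera adjusted p = 7.1e-05), among them VAMP8 (-4.79 ± 0.16) and COL4A1 (-2.41 ± 0.11). Of 27 cholesterol synthesis genes 16 were lower and 3 higher (16 and 3 adjusted over the list alone; median -0.30, camera adjusted p = 0.00011), among them INSIG1 (-1.25 ± 0.11). With an estimated correlation, the adjusted p of these 3 lists on DLL4 was 0.92. Of 38 replication-dependent histone genes listed only 10 were measured in this polyadenylated RNA, and whether they represent histone mRNA as a whole was not tested. Of these 10, 4 were lower and none higher on DLL4 (the same numbers adjusted over the list alone, median -0.61, camera adjusted p = 0.0015, adjusted p = 0.43 with an estimated correlation). HIST1H2BK (-2.67 ± 0.24) and HIST2H2AC (-1.16 ± 0.13) were the lowest by p. On IgG 3 were lower and none higher (the same numbers adjusted over the list alone; median -0.63, camera adjusted p = 0.039, adjusted p = 0.88 with an estimated correlation), a call that ended without NT library IgG 3 (adjusted p = 0.055), with median-of-ratios rescaling (0.059) and with quantile normalisation (0.081).

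In NKO cells 1418 genes differed from NT on IgG, 654 up and 764 down, and 2758 on DLL4, 1520 up and 1238 down. POSTN was at 61.8 ± 3.24 TPM on IgG (5.67 ± 0.15), AXL at 46.8 TPM (5.33 ± 0.29), GPX3 at 67.5 ± 2.39 (5.31 ± 0.22) and OCIAD2 at 128 ± 4.15 (5.12 ± 0.21). GPAT2 (4.95 ± 0.13), the fatty acid binding protein gene FABP5 (4.75 ± 0.25) and the proteoglycan gene BGN (4.54 ± 0.33) were higher too. G0S2, an inhibitor of lipolysis, was listed at 0 in both NT libraries on IgG and averaged 43.0 ± 1.63 TPM in NKO cells. COLEC10 (-4.69 ± 0.17), POPDC3 (-4.53 ± 0.16), the galanin gene GAL (-4.44 ± 0.24), MCF2L (-3.78 ± 0.22), P2RX5 (-3.65 ± 0.26), the growth factor IGF2 (-3.63 ± 0.17) and TFF1 (-3.39 ± 0.30) were lower. On DLL4 POSTN (5.77 ± 0.15), OCIAD2 (5.50 ± 0.21) and GPX3 (4.96 ± 0.22) were again among the highest. TFF1 (-5.93 ± 0.30), ACP5 (-3.81 ± 0.20), HES4 (-3.77 ± 0.19) and EFNB2 (-3.49 ± 0.19), all raised by DLL4 in NT cells, were among the lowest. Median-of-ratios rescaling turned the split on DLL4 to 1280 up and 1568 down. The count on IgG was 813, 664 and 820 without NT libraries IgG 2 and IgG 3 and NKO library IgG 1, and 424 in a fit of the 4 libraries compared. The count on DLL4 was 1693, 1454, 1450 and 1802 without NT libraries DLL4 2 and DLL4 3 and NKO libraries DLL4 1 and DLL4 2, and 1835 in a fit of the 4 libraries compared.

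Of the 19 Notch target genes 13 were lower and 2 higher in NKO than in NT cells on DLL4 (14 and 2 adjusted over the list alone; median -0.89, camera adjusted p = 4.1e-09, adjusted p = 0.24 with an estimated correlation). DLL4 (-1.90 ± 0.13), HEY2 (-1.31 ± 0.11), HEY1 (-1.19 ± 0.21) and JAG1 (-0.96 ± 0.17) were among the lower ones, and CCND1 (0.58 ± 0.13) was higher, a call that ended without NT library DLL4 3 (adjusted p = 0.081). On IgG 6 were lower and none higher (6 and 2 adjusted over the list alone; median -0.15, camera adjusted p = 0.019, adjusted p = 0.78 with an estimated correlation), with HES4 (-1.98 ± 0.19), HES1 (-0.87 ± 0.12), NOX4 (-1.29 ± 0.21) and UNC5B (-0.96 ± 0.17) the lowest by p. The call on IgG ended without NT library IgG 3 (adjusted p = 0.066) or NKO library IgG 1 (adjusted p = 0.058), with a stricter filter (0.065), median-of-ratios rescaling (0.054) or a replicate block (0.062). Of 47 proliferation genes 30 were higher and none lower on DLL4 (31 and none adjusted over the list alone; median 0.41, camera adjusted p = 5.3e-13, adjusted p = 0.33 with an estimated correlation), led by TYMS (1.13 ± 0.07) and E2F1 (1.28 ± 0.10). Of 10 replication-dependent histone genes 3 were lower and none higher there (the same numbers adjusted over the list alone; median -0.36, camera adjusted p = 0.024, adjusted p = 0.33 with an estimated correlation), with HIST1H2BK at -1.74 ± 0.24. The histone call ended without NT library DLL4 3 (adjusted p = 0.079), with a replicate block (0.11), median-of-ratios rescaling (0.053) or quantile normalisation (0.058). Of 23 arterial genes 13 were lower and 3 higher on DLL4 (15 and 4 adjusted over the list alone; median -0.75, camera adjusted p = 4.6e-07, adjusted p = 0.24 with an estimated correlation). Of 27 cholesterol synthesis genes 15 were lower and 1 higher (16 and 1 adjusted over the list alone; median -0.32, camera adjusted p = 5.7e-08, adjusted p = 0.33 with an estimated correlation), with INSIG1 at -0.91 ± 0.11. For the mesenchymal list on DLL4 the median (-0.18) and the test (lower, camera adjusted p = 0.026, adjusted p = 0.53 with an estimated correlation) had another sign than the mean (0.05), which POSTN and MYL9 (2.44 ± 0.13) raised. Of its 32 genes 7 were higher and 12 lower (8 and 14 adjusted over the list alone). This call ended without NT library DLL4 3 (adjusted p = 0.076) or NKO library DLL4 2 (0.058), with a replicate block (0.078) and without the genes of chromosomes 8, 11, 18 and 21 (0.071). Markers of smooth muscle cells and fibroblasts were lower on DLL4 as well: of 6 measured 2 were lower and none higher (3 and none adjusted over the list alone; median -0.31, camera adjusted p = 0.033, adjusted p = 0.33 with an estimated correlation), with RGS5 at -2.21 ± 0.12 and PDGFRL at -1.32 ± 0.16. That call ended without NT library DLL4 3 (adjusted p = 0.052), with a replicate block (0.11), with median-of-ratios rescaling (0.058) and without the genes of those 4 chromosomes (0.15), where the median was 0.02. Of 5 leukocyte markers measured 2 were lower and none higher on IgG (3 and none adjusted over the list alone; median -0.43, camera adjusted p = 0.0078, adjusted p = 0.50 with an estimated correlation), with LAPTM5 at -1.01 ± 0.07 and CORO1A at -0.81 ± 0.14.

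Both knockout lines differed from NT cells in many of the same genes. On IgG 426 genes were higher in both and 451 lower in both, against 99.3 and 94.6 for independent lists, and 60 differed in opposite directions. On DLL4 732 were higher in both and 663 lower in both, against 245 and 130 for independent lists, and 110 were opposite. POSTN, AXL, OCIAD2, GPX3 and GPAT2 were higher in both lines on IgG, and COLEC10 and MCF2L lower in both. Both lines were compared with the same NT libraries. In simulated data without any change this alone gave correlations across genes of 0.502 on IgG and 0.497 on DLL4. The correlations in the data were 0.597 and 0.605. The simulated groups held only noise, so their correlations do not show how much of those in the data came from shared libraries. The covariance across genes, which keeps the size of the differences, was 0.184 on IgG and 0.213 on DLL4. In simulated data it was 0.021 on both coatings. Between TKO on IgG and NKO on DLL4, which share no library, r was 0.426 with 492 genes higher in both, 473 lower in both and 283 opposite. Between TKO on DLL4 and NKO on IgG r was 0.469. Genes are not independent replicates, so these correlations carry no p. In all, 295 genes were higher and 294 lower in both lines on both coatings.

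Genes on some chromosomes differed together between the lines. In TKO against NT cells on IgG, the median over 585 protein-coding genes of chromosome 11 was 0.53, with 93.2% of them above 0, over 131 genes of chromosome 18 it was 0.52 and over 98 genes of chromosome 21 it was 0.48. On DLL4 the medians were 0.59, 0.48 and 0.49. In NKO cells the median over 328 genes of chromosome 8 was -0.20 on IgG and -0.16 on DLL4. Each of these was farther from 0 than in every one of 10000 random gene lists of that size (two-sided permutation p = 0.0002, the smallest they can give). The medians of all other chromosomes lay between -0.12 and 0.14 in these comparisons. The largest regional difference was at 105995623 to 118431496 of chromosome 11, where the median of 40 genes was 1.27 in TKO cells on both coatings, and 0.93 on IgG and 1.07 on DLL4 in NKO cells. Chromosome 8 differed in part: at 614746 to 22604150 the median in NKO cells was -0.53 on IgG and -0.58 on DLL4, and at 43140455 to 73048122 it was -0.37 and -0.34. At 89901849 to 103073051 it was 0.18 on IgG and 0.12 on DLL4. Of the genes called between TKO and NT cells 22.4% on IgG and 23.1% on DLL4 lay on chromosomes 8, 11, 18 or 21, which held 11.2% of the genes tested. SLC43A3 (4.75 ± 0.19 on IgG), on chromosome 11, was among the largest differences of TKO cells. Chromosomes 8, 11, 18 and 21 were chosen after their values were seen. Random lists were drawn for them alone, so the permutation p does not set them apart from the other chromosomes.

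**Figure D4:**
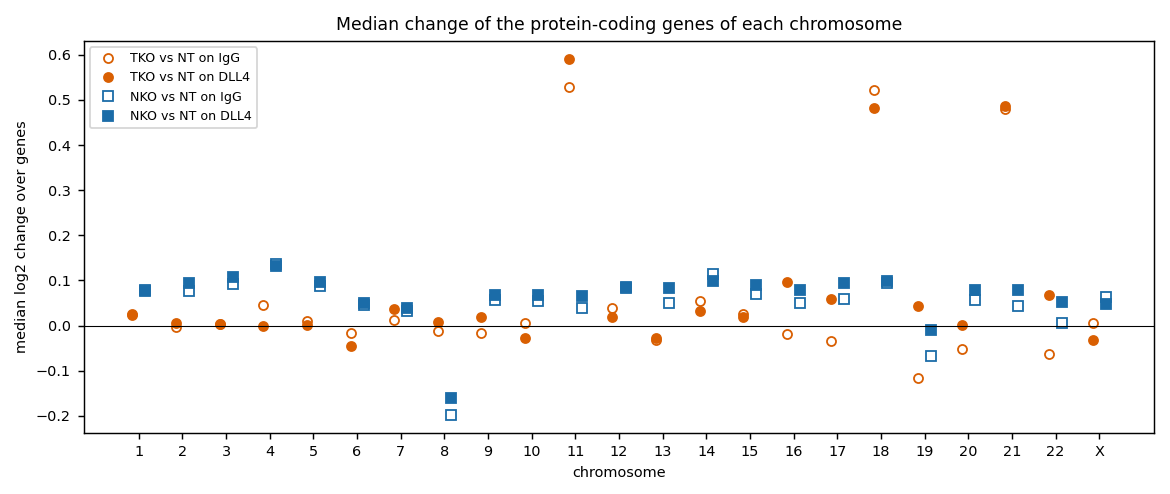
Median log2 difference of protein-coding genes per chromosome between each knockout line and NT on the same coating. On IgG chromosomes 11, 18 and 21 lay at 0.53, 0.52 and 0.48 in TKO cells and chromosome 8 at -0.20 in NKO cells.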

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

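The tests of a few strongly changed genes, of copy number and of loss of Notch signalling without shared libraries were chosen only after the result was seen, and the others were written before. The values of the next 3 paragraphs stood out because the response to DLL4 differed between lines in a test of that difference itself, and the 2 patterns after them are differences from NT cells that were weighed because of their extent.

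Between TKO and NT cells 70 genes responded differently. The median difference of responses (log2) was 0.25 for the ribosomal protein list, 0.23 for proliferation, -0.23 for the unfolded protein and ATF4 list, -0.34 for arterial genes, 0.16 for oxidative phosphorylation, -0.25 for mesenchymal genes, -0.18 for coronary artery disease loci, -0.33 for Notch targets, -0.19 for extracellular matrix, -0.14 for cholesterol synthesis, -0.18 for junctions, -0.20 for ADAM10 substrates and -0.14 for endothelial identity genes. The adjusted p of these lists was 0.377 to 0.605 with an estimated correlation, past which none of the calls was kept. Without TKO library IgG 3 the cholesterol (adjusted p = 0.131), junction (0.0982), ADAM10 substrate (0.0689) and endothelial identity (0.113) calls ended, the ADAM10 substrate call also without NT library IgG 2 (0.0668) and the endothelial identity call also without NT library IgG 2 (0.0935) or DLL4 2 (0.0597) or the genes of chromosomes 8, 11, 18 and 21 (0.0691). PDE1A (2.39), CA2 (2.20), MFNG (1.99), ART4 (1.55) and HES1 (1.43) had more positive responses in TKO cells, and PTGS2 (-2.69), IL33 (-2.67), GJA4 (-2.53), ACP5 (-2.50) and HEY2 (-1.30) more negative ones. GJA4 was listed at 0 in every IgG library, so its value rests on the pseudocount. That of ART4, whose IgG level was 0.0101 TPM in NT and 2.52 TPM in TKO cells, does too, since it was -0.74 with a pseudocount of 0.1, which also ended the calls of PDE1A (adjusted p = 0.166), GJA4 (0.111), ACP5 (0.0802) and PTGS2 (0.0525). The calls of MFNG, IL33 and ACP5 were kept whichever library was left out. Those of HES1, HEY2 and GJA4 ended without TKO library DLL4 3 (adjusted p at most 0.0531), that of HES1 also without NT library IgG 3 (0.0504). Those of PDE1A, CA2, ART4 and PTGS2 ended without any 1 of NT libraries IgG 2 (at most 0.101), IgG 3 (0.0813) and DLL4 2 (0.124) or TKO library DLL4 2 (0.113). All but PDE1A also ended without NT library DLL4 3 (at most 0.108), all but ART4 without TKO library IgG 3 (0.110), and ART4 and PTGS2 without TKO libraries IgG 2 (0.0554) or DLL4 3 (0.131).

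Between NKO and NT cells 118 genes responded differently. The median difference of responses was 0.22 for the ribosomal protein list, 0.31 for proliferation, -0.45 for arterial genes, -0.36 for mesenchymal genes, -0.77 for Notch targets, -0.24 for coronary artery disease loci, 0.11 for oxidative phosphorylation, -0.25 for extracellular matrix, -0.24 for junctions, -0.24 for cholesterol synthesis, -0.20 for endothelial identity, -0.23 for TGF-beta and BMP, -0.20 for mitochondrially encoded genes, -0.17 for ADAM10 substrates, -0.17 for p53 targets and -0.16 for shear stress and quiescence. The adjusted p of these lists was 0.224 to 0.638 with an estimated correlation. Single libraries ended the calls of shear stress and quiescence (adjusted p = 0.0649 without NT library IgG 2, 0.0625 and 0.152 without NKO libraries IgG 2 and DLL4 1), p53 targets (0.122 and 0.0827 without the same NKO libraries), TGF-beta and BMP (0.0545 without NT library IgG 2, 0.0760 without NKO library IgG 2), oxidative phosphorylation (0.142 without NKO library IgG 1) and mitochondrially encoded genes (0.147, 0.454, 0.166 and 0.586 without NT libraries IgG 3 and DLL4 3 and NKO libraries IgG 1 and DLL4 2). FST (2.31), CA2 (1.76), MFNG (1.655) and PTPN7 (1.64) had more positive responses in NKO cells, and EFNB2 (-3.17), ACP5 (-2.84), IL33 (-2.63), GJA4 (-2.61), DLL4 (-1.95), HES4 (-1.795) and HEY2 (-1.65) more negative ones. The calls of CA2 and PTPN7 ended without any 1 of the 4 NT libraries (adjusted p at most 0.184) or the 4 NKO libraries (at most 0.136), that of PTPN7 also without either TKO library on DLL4 (0.0706), and that of HES4 without NT libraries IgG 2 (0.0693) or DLL4 2 (0.0842) or NKO library DLL4 1 (0.0543). A pseudocount of 0.1 ended the calls of HES4 (0.180), GJA4 (0.0824), CA2 (0.0706) and PTPN7 (0.0642).

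Between NKO and TKO cells 20 genes responded differently. The median difference was 0.21 for the unfolded protein and ATF4 list, -0.24 for Notch targets, -0.17 for p53 targets, 0.08 (0.0777) for proliferation and -0.08 (-0.0811) for arterial genes, with adjusted p of 0.412 or more with an estimated correlation. The arterial call ended without TKO libraries IgG 3 (adjusted p = 0.0639) or DLL4 2 (0.0961) or NKO libraries IgG 2 (0.138), DLL4 1 (0.0705) or DLL4 2 (0.0562), with a replicate block (0.0647) and without the genes of chromosomes 8, 11, 18 and 21 (0.0692), and the proliferation call without TKO libraries IgG 2 (0.0832) or DLL4 3 (0.165) or NKO libraries IgG 2 (0.128) or DLL4 1 (0.117). ASNS (1.62), MT1E (1.42), FST (1.38) and RGCC (1.13) had more positive responses in NKO cells, and PDE1A (-3.11), ART4 (-2.31), EFNB2 (-2.23) and TMOD1 (-1.60) more negative ones. MT1E was listed at 0 in all 4 NKO libraries, so its value restates its decrease in TKO cells, from 206 to 76.3 TPM. With a pseudocount of 0.1 the calls of ART4 (adjusted p = 0.935), MT1E (0.754), EFNB2 (0.236), PDE1A (0.0552) and FST (0.0527) ended. Without NKO library DLL4 1 all of these calls but that of ART4 ended (adjusted p at most 0.178). Without TKO library DLL4 2 those of MT1E, FST, RGCC, EFNB2 and TMOD1 ended (at most 0.188), and without TKO library DLL4 3 the same but EFNB2 (at most 0.142). Without TKO library IgG 2 the calls of MT1E, FST and RGCC ended (at most 0.112), without TKO library IgG 3 those of MT1E, RGCC and TMOD1 (at most 0.0864), without NKO library IgG 2 that of FST (0.140), without NKO library DLL4 2 those of RGCC (0.1001) and TMOD1 (0.0505), and without any 1 of the 4 NT libraries those of FST and RGCC (at most 0.0895).

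Genes of chromosomes 11, 18 and 21 were higher as a whole in TKO than in NT cells. After a trend on GC content and transcript length was removed the smallest of the medians on IgG was 0.464, which argues against such a bias as the whole cause, and the smallest share of genes above 0 was 91.8%, which argues against a few strongly changed genes. A difference in chromosome copy number between the cell lines remains a candidate explanation. DLL4 against IgG within a line moved these chromosomes by at most 0.0502, and their TKO medians differed between coatings by at most 0.0622. Any lasting difference between the lines would give such values, so they argue only against an effect of the ligand and do not favour copy number. No DNA was measured, and whether such a difference would come from the edit, from the choice of clones or from culture was not tested.

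Genes that differed from NT the same way in both knockout lines numbered 877 on IgG and 1395 on DLL4. Chance values of the shared NT libraries are argued against by a correlation across genes of 0.426 between TKO on IgG and NKO on DLL4, which share no library. Loss of Notch signalling in both lines would make most of these genes the reverse of the DLL4 response in NT cells. In the test written before, 126 of the 877 were called the opposite way for DLL4 in NT cells and 145 the same way. On DLL4, a count added later, 572 of the 1395 were called the opposite way. Both sides of these counts use the same NT libraries, which pushes them to the same way on IgG and to the opposite way on DLL4, so they decide nothing. The knockouts were therefore compared with 1 NT library of a coating and that response was measured with the other. Of 454 and 514 genes then called the same way in both lines on IgG, 51.1% and 51.2% had a response of the opposite sign, which argues against such a loss as the cause of most of them, and a part stays open. On DLL4 it was 77.8% of 823 and 74.2% of 885 genes, on both sides of the 75% bound set for IgG, so there a loss of Notch signalling stays open as a candidate explanation. All these shares also count genes whose own DLL4 response was not called. Among those with a called response the opposite way was the more frequent on both coatings, slightly on IgG and by far on DLL4. On chromosomes 8, 11, 18 or 21 lay 15.2% of the genes shared on IgG, against 11.2% of the genes tested. On IgG the medians of chromosomes 11, 18 and 21 were 0.04, 0.09 and 0.04 in NKO cells. That of chromosome 8 was -0.01 in TKO cells. Shifts of these whole chromosomes were thus not shared by both lines, so a low share was bound to follow and decides nothing about shared regions. The region of chromosome 11 at 105995623 to 118431496 was higher in both lines, with a median of 1.27 in TKO cells on both coatings. In NKO cells its median was 0.93 on IgG and 1.07 on DLL4. How many of the shared genes lie there, and whether NT cells were the line that differed, was not tested. A property of the NT line, a shared effect of editing or selection, and an effect of both targeted genes outside the DLL4 response were not tested and stay open.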

How the results depend on the processing

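Leaving out KPNA2P2 or the genes of chromosomes 8, 11, 18 and 21, and, for lists other than the Notch targets, both scalings and the left-out libraries, were added after the data were seen; the other alternatives were planned. Of the counts of genes called under alternatives, 164 stayed within 1.5 times the reported count and 56 did not. A fit of only the libraries compared called 1085 genes for DLL4 in NT, 166 in TKO and 0 in NKO cells (limma; 865 at an unadjusted p under 0.05), 2245 for TKO and 424 for NKO against NT on IgG, 1835 for NKO against NT on DLL4, 70 for NKO minus NT responses and 0 for NKO minus TKO (limma; 681 unadjusted). This fit has fewer residual degrees of freedom. For TKO minus NT responses the stricter filter called 108 genes and quantile normalisation 141, and without a filter 78 genes were called for NKO minus NT and 33 for NKO minus TKO; the cause was not tested.

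With a library left out, a group of 1 library is assumed to vary like the others, and fewer libraries estimate the spread. In every comparison, also for DLL4 within a line, some named genes lost their call without some library. Not all of these are listed above. The counts then ran from 958 to 2380 for DLL4 in NT, 302 to 1017 in TKO and 37 to 116 in NKO cells. They ran from 2424 to 3909 for TKO against NT on IgG and 2315 to 3716 on DLL4, from 664 to 1579 for NKO against NT on IgG and 1450 to 2991 on DLL4. Between responses they ran from 8 to 100 for TKO minus NT, 31 to 107 for NKO minus NT and 2 to 19 for NKO minus TKO. The adjusted p of the Notch target list ran from 6.1e-07 to 1.6e-05 for DLL4 in NT, 0.000501 to 0.0104 in TKO and 0.0458 to 0.436 in NKO cells, from 0.327 to 0.674 for TKO against NT on IgG and 0.344 to 0.625 on DLL4, from 0.0110 to 0.0655 for NKO against NT on IgG and 1.0e-09 to 1.3e-08 on DLL4, and from 0.00131 to 0.0169 for TKO minus NT, 3.1e-08 to 7.6e-05 for NKO minus NT and 6.9e-05 to 0.00758 for NKO minus TKO. The retained response ran from 30.6% to 44.6% in TKO and 24.9% to 34.3% in NKO cells.

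With an estimated correlation the Notch target list had an adjusted p of 0.264 for DLL4 in NT, 0.518 in TKO, 0.779 for NKO against NT on IgG and 0.244 on DLL4, 0.497 for TKO minus NT, 0.224 for NKO minus NT and 0.601 for NKO minus TKO. Its estimated correlation of 0.158 exceeds the preset. With the stricter filter it was 0.123 in TKO, 0.0648 for NKO against NT on IgG and 0.227 for TKO minus NT, and without a filter 0.0267 in NKO cells. Without the 4 chromosomes it was 0.000738 for DLL4 in NKO and 0.0408 for TKO against NT on DLL4. By fry it was 0.0319 for TKO against NT on IgG and 0.101 for NKO minus TKO. For NKO against NT on IgG it was 0.0540 by camera with median-of-ratios rescaling and 0.0615 with a replicate block. Some of these settings changed the list itself. HEY1, SOX17 and MYC lie on chromosome 8 and CCND1 and NOX4 on chromosome 11, so they were missing without the 4 chromosomes. The stricter filter left out members at low levels, such as EFNB2, HEY1, GJA4 and TMEM100. How far this accounts for the changed p, and the cause of the other changes, was not tested. Of all 30 lists fry called 4 for TKO minus NT, 3 for NKO minus NT and 0 for NKO minus TKO, where camera called 13, 16 and 5. The retained response in TKO cells was 39.9% with a pseudocount of 0.1, and 54.3% and 53.6% with genes chosen on 1 NT library of each coating and measured on the other, as was 39.6% in NKO cells (both the genes and the measuring libraries differ there, and the 2 were not separated).

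Of the values of named genes, 15105 stayed on their side of the threshold (76 of them, not called, changed sign), 1088 lost a call, 163 gained one and ART4 reversed with a pseudocount of 0.1 (-0.74 for TKO minus NT). Of those of other lists, 4662 stayed on their side (192, not called, changed sign), 189 lost a call, 77 gained one and 2 reversed. These were the ribosomal protein list for NKO minus TKO without IgG_TKO replicate 3 (adjusted p = 0.000326; 9.0e-09 to 0.941 over the left-out libraries) and the mitochondrially encoded list for DLL4 in NKO cells without DLL4_NKO replicate 2 (0.644; 2.0e-06 to 0.654). No scaling moved the median of all genes by more than 0.1. After group means were removed, libraries with the same number correlated at r of -0.154 to 0.279. The highest value was that between the coatings of NKO cells, against -0.0003 in NT and 0.016 in TKO cells. Of the 12 libraries 8 correlated best with a library of their own number. The 2 libraries of a group deviate from their mean by equal and opposite amounts, so these libraries do not count separately. A pairing within the NKO line thus cannot be excluded, and the main fit took none into account. The unknown depth limits what can be said of genes near 0 TPM.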

Other observations

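Both tests on KPNA2P2 were chosen only after the result was seen. Other gene groups also changed on DLL4 in NT cells. Of 30 p53 target genes 9 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.26, camera adjusted p = 0.00027, adjusted p = 0.33 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 0.86 ± 0.09 and TP53INP1 at 1.25 ± 0.21. Of 28 genes of TGF-beta and BMP signalling 10 rose and 2 fell (11 and 4 adjusted over the list alone; median 0.35, camera adjusted p = 0.0020, adjusted p = 0.42 with an estimated correlation), among them the receptor gene TGFBR2 (0.98 ± 0.12), SMAD6, an inhibitor of BMP signalling (1.36 ± 0.24), and ID1 (-0.84 ± 0.13). Of 27 junction and barrier genes 11 rose and 3 fell (13 and 3 adjusted over the list alone; median 0.28, camera adjusted p = 0.0026, adjusted p = 0.49 with an estimated correlation), with TJP1, a tight junction scaffold, up (0.87 ± 0.11) and the claudin gene CLDN5 down (-1.76 ± 0.16). Of 12 venous genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.48, camera adjusted p = 0.016, adjusted p = 0.42 with an estimated correlation), including EPHB4, the receptor of EFNB2 (0.87 ± 0.11). Of 24 immediate early and heat shock genes 7 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.18, camera adjusted p = 0.0036, adjusted p = 0.47 with an estimated correlation), with EGR1 at -1.51 ± 0.25, and the one that rose was DUSP6, a phosphatase of ERK (1.32 ± 0.10).

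Between the lines, 12 of 33 genes of the unfolded protein and ATF4 response were higher and 2 lower in TKO than in NT cells on IgG (12 and 2 adjusted over the list alone; median 0.25, camera adjusted p = 0.030, adjusted p = 0.88 with an estimated correlation), with CHAC1 (1.20 ± 0.16) and ASNS (0.69 ± 0.12) highest by p together with ATF4 (0.39 ± 0.07). That call ended without TKO library IgG 2 (adjusted p = 0.066). Of 23 tetraspanin genes measured, 7 were lower and 3 higher in NKO than in NT cells on DLL4 (8 and 4 adjusted over the list alone; median -0.15, camera adjusted p = 0.018, adjusted p = 0.33 with an estimated correlation), with CD82 (-1.31 ± 0.12) and TSPAN33, a TspanC8 tetraspanin (-1.42 ± 0.18), the lowest by p. Of 29 inflammatory genes 11 were lower and 5 higher there (12 and 6 adjusted over the list alone; median -0.29, camera adjusted p = 0.0079, adjusted p = 0.35 with an estimated correlation), among them IL32 (-1.92 ± 0.09) and CXCL1 (-1.48 ± 0.11), with BCL2A1 higher (1.54 ± 0.17). Without NT library DLL4 3 both of these calls ended (adjusted p = 0.052), and the tetraspanin call ended with a replicate block (0.065) and without the genes of chromosomes 8, 11, 18 and 21 (0.055).

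KPNA2P2 is a pseudogene entry on the minus strand of chromosome 7 (88564793 to 88566281) that was listed at 2734 to 54830 TPM, or 0.280% to 5.61% of a library. It differed within groups, as at 3214 and 30357 TPM in the NT libraries on DLL4. Reads of its parent gene KPNA2, at 277 to 377 TPM, are argued against, since KPNA2P2 exceeded KPNA2 in 12 of 12 libraries. Its transcript holds an unbroken run of 21 C or G, and reads made of such a run are a candidate explanation: the other 16 symbols with a run of at least 17 had a median Spearman rho of 0.5 with KPNA2P2 across the libraries, exactly the bound written for it, against -0.077 for 13882 symbols without a run. Of the 16, 8 had a rho of at least 0.71, among them PROCA1, ANKRD34A, HIPK2 and KLF15, and the others were at most 0.29, and none of those 8 genes is named in a comparison here.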
